A study of Homo sapiens with 4 samples.

How the data were processed

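RNA from 4 HepG2 cultures was measured on 1-colour Affymetrix arrays, 2 after anti-miR-191 and 2 after a negative control anti-miR, per the labels. Cells were transfected with a lipid reagent and total RNA was extracted with a commercial kit, and DNA was labelled with biotin by terminal transferase, per the labels' protocols. The authors deposited 1 table of log2 intensity values, made with RMA in Affymetrix Expression Console, per the submitters' processing notes. RMA corrects background, normalizes arrays and summarizes the probes of each transcript cluster. The version, the annotation release and which arrays were normalized together are not given in the sources used here. The base of the logarithm was taken from RMA's usual output and the range of the values. RMA intensity has no counting depth, so precision is limited by the number of arrays.

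The table holds 33297 rows. GEO's platform annotation, dated 2016, gave 1 gene symbol for 19460 rows, several for 1754 and none for 12083, and rows with several or none were not named. Of the rows with 1 symbol, 19429 had their Entrez identifier in the RefSeq gene table of assembly GRCh38.p14, used for names and, for 14134 of the genes tested, for the genomic span, and 0 symbols needed updating. No genome sequence was used, so no coordinates are given and the planned test of miR-191 seed sites in 3' UTRs was not run. The 33.3% of rows with the lowest mean level over the 4 arrays (below 3.41) were left out, and a gene with several rows was represented by the brightest. This left 14147 genes.

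The main tests were limma 3.58.1 fits (lmFit and eBayes with default settings, R 4.3.3), two-sided, with Benjamini-Hochberg adjustment over all genes tested and a threshold of 0.05. The unpaired fit compared the groups alone, with 2 residual degrees of freedom. The paired fit kept the experiment as a block, with 1 residual degree of freedom. Moderation across genes added 4.32 and 6.60 prior degrees of freedom. The pairing comes from the series text, which places the duplicate treatments in independent studies, and from the titles, which number both groups 1 and 2. Deviations of same-numbered arrays from their group means correlated at 0.335 across the genes tested. With 2 arrays per group the deviations of both pairs mirror each other, so this is a single value. Gene lists were tested with camera at its preset correlation of 0.01, with Benjamini-Hochberg adjustment over the 29 of 31 lists with at least 5 tested members. The 31 lists, the tests and the rule for named genes were fixed before the data were examined. Of 585 list entries, 517 were on the array with 1 symbol. Correlations of the 2 experiments' changes are descriptions across genes.

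The named genes are, by the fixed rule, the 15 higher and 15 lower genes with the largest smaller-of-both change among genes past the threshold in either fit with the same sign in both experiments. Of each list described, up to 4 members with the largest mean change and up to 10 members past the threshold are named. MIR191, MIR425 and DALRD3 are named whatever their values. ALB, APOB, ASNS, BAX, FOS, MDM2, PSAT1, SC5D and the markers used to judge background were named after their values were seen. Alternatives covered the block, the filter on dim rows, the scaling between arrays (median centring, quantile normalization and cyclic loess), the moderation, the rows tested, the fold and p thresholds, the set test and single arrays left out.

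The fits were run on simulated data drawn from the real means and experiment differences of the 14147 genes, with their spreads exchanged between genes and averaged with the mean spread, with 200 genes changed. For the paired fit, 100% of genes with a log2 change of 2, 75.8% of those with a change of 1 and 15.3% of those with a change of 0.585 were called, and 24 of 13947 unchanged genes were called. For the unpaired fit the shares were 96.2%, 6.45% and 0%, with 1 unchanged gene called. Camera called the 1 shifted set and 0 of 30 unshifted sets. The noise was drawn independently for each gene, so this does not show how often lists of correlated genes are called in error. The unpaired p-values measure the spread between 2 arrays per group. The paired p-values measure how far the changes of the 2 experiments differ from each other. In each fit this spread is moderated across genes. Figures were drawn with matplotlib 3.10.9.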

Results

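Gene expression was measured in HepG2 cells, an established hepatocellular carcinoma line, after transfection with an antisense inhibitor of miR-191 (anti-miR-191) or with a negative control anti-miR. RNA was profiled on 4 Affymetrix arrays, 2 per group. The treatment was carried out in 2 independent experiments, so that each experiment gave 1 anti-miR-191 array and 1 control array. The comparison asks which transcripts differ when miR-191 is inhibited. The deposited values were RMA intensities on the log2 scale, with array medians between 4.37 and 4.43. The interquartile range was 3.38 and 3.43 on the anti-miR-191 arrays and 3.18 and 3.24 on the control arrays. Changes are given below as anti-miR-191 minus control on the log2 scale, as the mean of the 2 experiments ± SE, and each rests on 2 arrays per group. A gene is said to have risen or fallen when its adjusted p was under 0.05 in the paired fit, which keeps the experiment as a block. The unpaired fit, which compares the groups without the experiment, stands beside it.

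The transcripts of the miR-191 locus did not pass the test. The probe set for the precursor MIR191 read 5.18 ± 0.06 (SD, n = 2) after anti-miR-191 and 4.86 ± 0.16 (SD, n = 2) in controls, a change of 0.32 ± 0.15 with limma's adjusted p = 0.201. In controls it lay below KRT14 (5.39), a marker of another cell type, so MIR191 is not shown to be above background. MIR425, the neighbouring microRNA, had changes of -0.27 in experiment 1 and 0.71 in experiment 2. The host gene DALRD3 had a change of -0.16 ± 0.15. An anti-miR binds the mature microRNA, which these probe sets do not measure apart from its precursor, so these values do not check the inhibition.

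The genes with the largest rises after anti-miR-191 included a target of the aryl hydrocarbon receptor, transcription factors of the early stress response and secreted growth factors. CYP1A1, a monooxygenase induced through the aryl hydrocarbon receptor, rose 10.6-fold (3.40 ± 0.24, with changes of 2.86 and 3.94 in experiments 1 and 2). TIPARP, another gene induced by that receptor, rose 4.49-fold (2.17 ± 0.14). The arrestin-domain gene ARRDC3 rose 9.58-fold (3.26 ± 0.17) from a control level of 3.63, close to the level of 3.41 below which rows were left out. DUSP1, a phosphatase that inactivates MAP kinases, rose 6.95-fold (2.80 ± 0.22). The transcription factors JUN, ATF3 and KLF6 rose 5.85-fold, 5.53-fold and 4.96-fold. HBEGF, a ligand of the EGF receptor, rose 5.91-fold, and the cytokine LIF rose 5.69-fold. The protease inhibitor SERPINE2 rose 5.54-fold. The others of the 15 highest-ranked genes were CLIP4, the pseudogene CENPBD1P (6.70-fold), NABP1 (6.11-fold), PIP5K1A (5.11-fold) and JMJD1C (4.56-fold). CLIP4 read 5.81 after anti-miR-191 and 3.05 in controls, a control level below the limit of 3.41 for dim rows, so no fold is given for it. JMJD1C and SERPINE2 had control levels of 3.76 and 3.84. Probe sets for markers of other cell types read as much in controls (HBB 3.66, VWF 3.70, THY1 3.76), so the control levels of ARRDC3, JMJD1C and SERPINE2 are not shown to be above background. These markers ranged from 3.42 (COL6A3) to 9.24 (LYZ) and set no single limit. ATF3 (4.67), CENPBD1P (4.79) and TIPARP (4.95) lay below KRT14 (5.39) in controls and are not shown to be above background either. The same holds for TNFAIP3, CCL20, CTH, SOCS3, BIRC2, AGO3, TNRC6A and CDC25C, named below, with control levels between 4.57 and 5.24. All 15 passed in both fits, with limma's adjusted p between 0.00090 and 0.0012 in the paired fit and between 0.012 and 0.026 in the unpaired fit.

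The genes with the largest falls included nuclear-encoded subunits of the respiratory chain and products typical of liver or epithelium. LCN15, a lipocalin, fell by 2.07 ± 0.19 on the log2 scale (-1.72 and -2.42 in experiments 1 and 2). NDUFA2 of complex I fell by 1.62 ± 0.14, UQCRQ of complex III fell by 1.56 ± 0.15 and COX7C of complex IV fell by 1.37 ± 0.14. HAMP, which encodes the iron-regulating liver hormone hepcidin, fell by 1.29 ± 0.15, and the antimicrobial peptide gene DEFB1 fell by 1.53 ± 0.15. The histone gene H2AC4, whose near-identical copies can share probes, fell by 1.62 ± 0.16. BST2, an interferon-induced antiviral membrane protein, fell 2.46-fold. MGST3, a microsomal glutathione transferase, fell by 1.74 ± 0.19, and TMEM141 fell by 1.82 ± 0.22. TMEM258, GPHA2, GDPD3, SMCO4 and RTL8C fell by between 1.23 and 1.41. The adjusted p of these 15 genes lay between 0.0017 and 0.0036 in the paired fit. In the unpaired fit LCN15, DEFB1, MGST3 and RTL8C did not pass (adjusted p = 0.062, 0.072, 0.061 and 0.145).

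**Figure D1:**
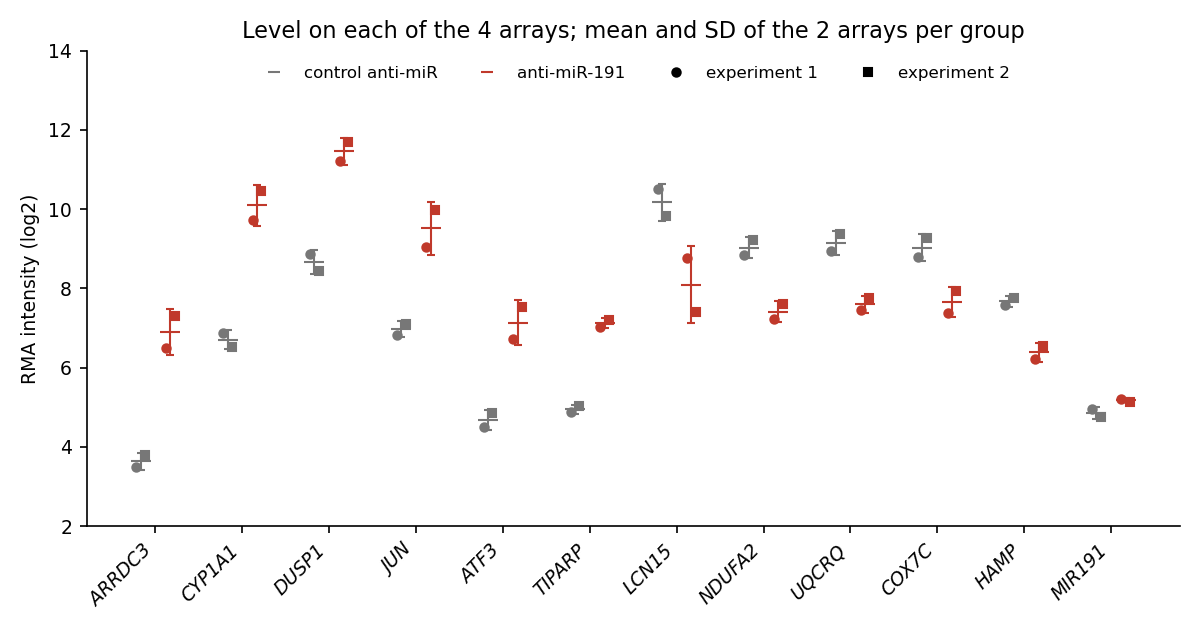
RMA intensity (log2) of 12 genes on the 4 arrays, grey for control anti-miR and red for anti-miR-191, with circles for experiment 1, squares for experiment 2, and bars for the mean and SD of 2 arrays. CYP1A1 stands at 10.1 against 6.70 in controls and NDUFA2 at 7.42 against 9.03. MIR191 stands at 5.18 against 4.86, a control level not shown to be above background.

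Over all 14147 genes tested, 1961 passed in the paired fit, of which 1428 were higher and 533 lower after anti-miR-191. Of these, 1780 changed by at least 1.5-fold. The unpaired fit called 553 genes, 452 higher and 101 lower, and all 553 were also called in the paired fit. After quantile normalization the unpaired fit called 548 genes, 385 higher and 163 lower, and the paired fit called 896 higher and 523 lower, so the share of higher genes depends on the scaling. The unpaired count also depended on single arrays. It was 339 without the anti-miR-191 array of experiment 1, and 0 without the anti-miR-191 array of experiment 2, without the control of experiment 1 or without the control of experiment 2. At an unadjusted p under 0.05, limma still counted 1663, 2432 and 3178 genes in those last 3 settings. Splitting the arrays by experiment gave 0 genes in limma's unpaired fit (356 at an unadjusted p under 0.05), and crossing the groups also gave 0 (85 at an unadjusted p under 0.05). Such splits leave the treatment difference in the residual, which lowers their counts, so they cannot show that the experiments do not differ. Among named list members, AHR, FOS, GCLC, NDST1, ORM2, RPL27A, SLC30A1 and TNRC6A lost their call in the paired fit under median centring, quantile normalization and cyclic loess alike (adjusted p between 0.051 and 0.114). CDT1 and SKIL lost it under median centring, NDUFB5, RPS14 and SLBP under cyclic loess, and under quantile normalization so did ARNT, AXIN2, BIRC2, BMF, CDKN1A, CHAC1, CYP27A1, DNAJB9, FOSL1, GLUL, H1-2, MT1G, NDRG1, NDUFB5, PRKRA, RPS14, SKIL, SLBP and TNFRSF10A.

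The changes of the 2 experiments went together across genes, with Pearson r = 0.678 and Spearman rho = 0.578. Genes are not independent replicates, so no p-value is attached. In both experiments 913 genes were at least 1.5-fold higher and 314 at least 1.5-fold lower, while 25 genes changed by as much in opposite ways. After quantile normalization the genes changed the same way were 716 higher and 408 lower. A change of at least 4-fold in both experiments was seen for 22 genes, all of them higher. The SD of the changes over genes was 0.430 in experiment 1 and 0.497 in experiment 2.

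**Figure D2:**
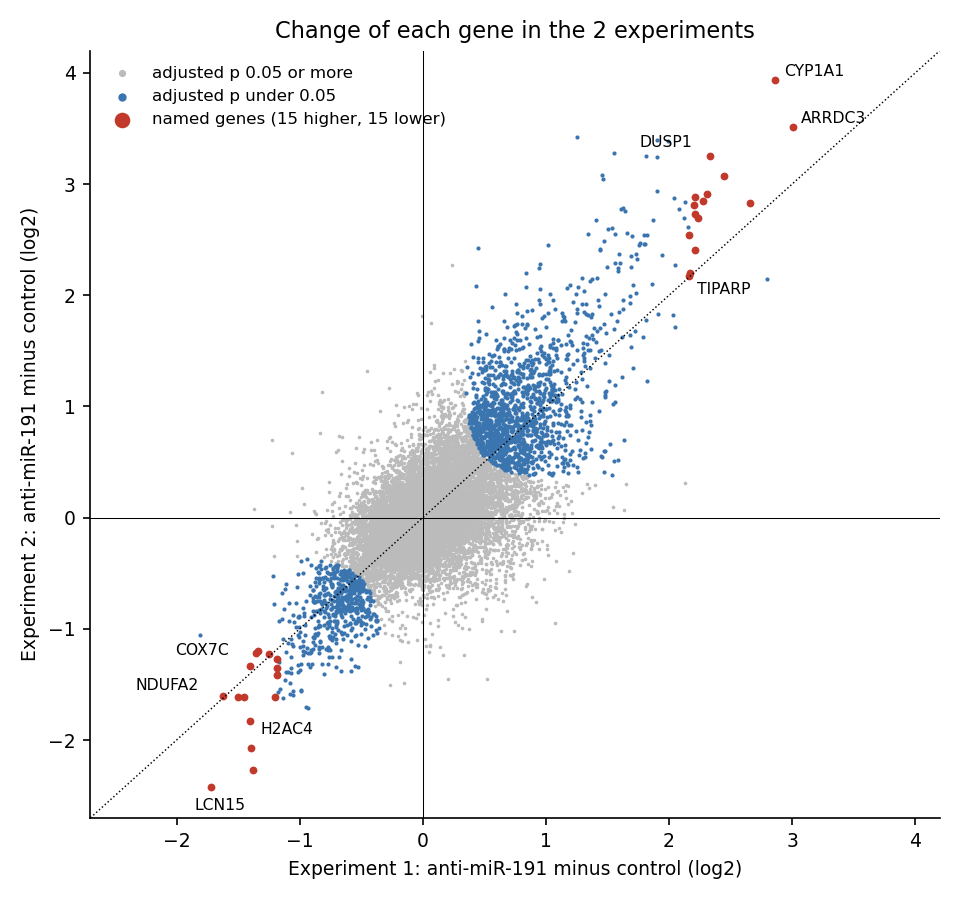
Change of each of 14147 genes (anti-miR-191 minus control, log2) in experiment 1 on the horizontal axis and in experiment 2 on the vertical axis, 1 point per gene, blue where the paired fit's adjusted p was under 0.05 and red for the 30 named genes. The changes of the 2 experiments correlate (Pearson r = 0.678). The line of greatest spread of the points has a slope of 1.24, steeper than the dotted line of equal change, so changes ran larger in experiment 2. The 15 named higher genes lie above 2 in both experiments.

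Immediate early genes, which respond first to growth factors and stress, rose together. Of 20 tested, 16 rose and 0 fell in the paired fit, with 14 higher in the unpaired fit and 19 higher when adjusted over the list alone in either fit. The list's median change was 1.46 in experiment 1 and 2.14 in experiment 2. JUNB rose 5.96-fold, the early growth response factor EGR1 rose 4.19-fold, IER2 rose 4.11-fold and KLF10 rose 3.93-fold. FOSB rose 3.79-fold, the survival gene MCL1 rose 3.69-fold and MYC rose 3.36-fold. FOS itself, named after its values were seen, had changes of 0.45 and 2.43 in experiments 1 and 2, and its adjusted p of 0.047 rose to between 0.061 and 0.167 under the alternatives that ended its call. The list stood apart from other genes by limma's camera test with a preset correlation (adjusted p = 1.2e-15, paired fit). Its adjusted p = 0.503 with an estimated correlation. The same holds for each of the 17 lists called in the paired fit, all of which had an adjusted p = 0.503 with an estimated correlation, a test that here has 1 residual degree of freedom.

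Part of the genes on the amino acid and p53 lists was also higher. Of 18 genes induced by amino acid shortage, 9 rose and 1 fell (6 higher in the unpaired fit, and 12 and 1 adjusted over the list alone), and the median change was 0.68 (camera adjusted p = 1.4e-05 with the preset correlation; adjusted p = 0.503 with an estimated correlation). ATF3, named above, is a member. The stress sensor SESN2 rose 4.50-fold, CTH rose 3.02-fold, the mTOR inhibitor DDIT4 rose 2.63-fold, CEBPG rose 2.53-fold, the cystine transporter SLC7A11 rose 2.44-fold and the pseudokinase TRIB3 rose 2.20-fold. CHAC1 and SLC3A2 rose 1.79-fold and 1.75-fold, whereas PHGDH, the first enzyme of serine synthesis, fell by 0.99 ± 0.16. Of 23 p53 target genes 9 rose and 0 fell (5 higher in the unpaired fit, and 11 higher adjusted over the list alone), with a median change of 0.42 (camera adjusted p = 0.00012; adjusted p = 0.503 with an estimated correlation). GADD45A rose 3.96-fold, the death receptor gene TNFRSF10B rose 2.99-fold, PLK3 rose 2.63-fold and ZMAT3 rose 2.41-fold. POLH and GDF15 rose 2.13-fold and 1.98-fold. RRM2B rose from a control level of 4.32, not shown to be above background, to 5.15. The cell cycle inhibitor CDKN1A rose 1.64-fold. SESN2 belongs to both lists. The other 14 p53 targets did not pass in the paired fit, among them MDM2 (0.37 ± 0.17) and BAX (-0.07 ± 0.14). Nor did 8 of the amino acid genes, among them ASNS (0.32 ± 0.14) and PSAT1 (-0.02 ± 0.14). A rise of part of a list does not show which pathway was active.

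Regulators of apoptosis and genes of the unfolded protein response were higher on balance. Of 22 apoptosis genes 7 rose and 1 fell (2 higher in the unpaired fit, and 11 and 1 adjusted over the list alone), with a median change of 0.47 (0.23 in experiment 1 and 0.67 in experiment 2; camera adjusted p = 0.0070; adjusted p = 0.503 with an estimated correlation). The risen members act both ways. MCL1 and BIRC2 (1.77-fold) oppose cell death, while BMF (1.63-fold), TNFRSF10A (1.60-fold), TNFRSF10B, PMAIP1 and APAF1 promote it. PMAIP1 read 5.25 against 4.41 in controls and APAF1 4.32 against 3.59, control levels not shown to be above background. BID, which also promotes cell death, fell by 0.58 ± 0.14. Of 18 genes of the unfolded protein response, 7 rose and 1 fell, also adjusted over the list alone, and 4 were higher in the unpaired fit (camera adjusted p = 0.010; adjusted p = 0.503 with an estimated correlation). Its median change was 0.55 in experiment 1 and 0.18 in experiment 2. Its largest rises were in ATF3, in DDIT3, which rose 4.60-fold, and in PPP1R15A, which rose 3.94-fold. TRIB3 is a member of this list as well. XBP1 and HERPUD1 rose 1.67-fold and 1.56-fold, and DNAJB9 rose from a control level of 3.85, not shown to be above background, to 4.69, while the chaperone partner SDF2L1 fell by 0.94 ± 0.21. Without the control array of experiment 1, the list lost its call in the unpaired fit (adjusted p = 0.117).

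Targets of NF-kB, hypoxia genes and genes of the aryl hydrocarbon receptor rose in part. Of 11 NF-kB and acute phase genes 6 rose and 1 fell, also adjusted over the list alone (camera adjusted p = 0.013; adjusted p = 0.503 with an estimated correlation). The inhibitors of the pathway TNFAIP3 and NFKBIA rose 5.22-fold and 4.16-fold, SOCS3 rose 2.78-fold, the chemokine CCL20 rose 2.49-fold, RELB rose 2.32-fold and ICAM1 rose 1.66-fold. The acute phase gene ORM2 fell by 0.56 ± 0.15. With dim rows kept, this list had a median change of -0.03 and an adjusted p of 0.063. Of 24 hypoxia and glycolysis genes 6 rose and 0 fell (3 higher in the unpaired fit, and 8 higher adjusted over the list alone; camera adjusted p = 0.0082; adjusted p = 0.503 with an estimated correlation). They were ADM (5.49-fold), VEGFA (2.93-fold), DDIT4, PFKFB3 (2.21-fold), KDM3A (level 4.77 against a dim 4.03 in controls) and NDRG1 (1.53-fold). Of 9 genes of the aryl hydrocarbon receptor and xenobiotic list 4 rose and 0 fell, also adjusted over the list alone, and 2 were higher in the unpaired fit (camera adjusted p = 0.041; adjusted p = 0.503 with an estimated correlation). The list had a median change of 0.81 in experiment 1 and 0.16 in experiment 2. Besides CYP1A1 and TIPARP the risen genes were the receptor gene AHR (1.92-fold, changes of 1.47 and 0.41) and its partner ARNT (1.89-fold). Leaving out the dimmer rows up to the median level ended this list's call (adjusted p = 0.078), as did leaving out the control array of experiment 1 in the unpaired fit (adjusted p = 0.088).

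TGF-beta and Wnt target lists passed in the paired fit and missed the threshold in the unpaired fit. Of 18 TGF-beta and mesenchymal genes 6 rose and 1 fell, also adjusted over the list alone, and 3 were higher in the unpaired fit (camera adjusted p = 0.043; adjusted p = 0.503 with an estimated correlation). CCN1 rose 5.31-fold, SNAI1 rose 4.61-fold, the inhibitory SMAD7 rose 4.38-fold, THBS1 rose 2.22-fold and CCN2 rose 1.70-fold. SKIL rose from a control level of 3.81, not shown to be above background, to 4.73, while ACTA2 fell by 0.66 ± 0.14. Of 15 Wnt targets 5 rose and 0 fell, also adjusted over the list alone, and 1 was higher in the unpaired fit (camera adjusted p = 0.024; adjusted p = 0.503 with an estimated correlation). The Wnt antagonist DKK1 rose 4.85-fold, TBX3 rose 1.98-fold, AXIN2 rose 1.58-fold and GLUL rose 1.49-fold, beside MYC. The unpaired fit gave adjusted p = 0.103 for the TGF-beta list, with 0.044 and 0.036 without the anti-miR-191 array of experiment 1 or 2. It gave 0.051 for the Wnt list, with 0.023 without the anti-miR-191 array of experiment 1, 0.044 without the control of experiment 2, 0.043 after median centring and 0.042 with dim rows kept. With dimmer rows left out up to the median level, both had an adjusted p of 0.056 in the paired fit.

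Genes recalled as targets of miR-191 from general knowledge were higher. The list was written without a source at hand, and whether earlier work chose any member on these samples is not known here. Of 18 genes recalled, 11 were tested and the others were left out as dim. Of the 11, 5 rose and 0 fell in the paired fit, 4 rose in the unpaired fit, and 7 were higher adjusted over the list alone in the paired fit. At an unadjusted p under 0.05, limma's paired fit had 8 higher and 1 lower. The median change was 0.56 in experiment 1 and 0.36 in experiment 2 (camera adjusted p = 0.0041; adjusted p = 0.503 with an estimated correlation). The risen members were EGR1, the transcription factor CEBPB (3.12-fold), SOX4 (2.18-fold), the Wnt receptor FZD5 (2.09-fold) and the heparan sulfate enzyme NDST1 (1.65-fold). Of 15 genes of microRNA processing 5 rose and 0 fell, also adjusted over the list alone, and 1 was higher in the unpaired fit (camera adjusted p = 0.043; adjusted p = 0.503 with an estimated correlation). AGO2 rose 1.83-fold, DGCR8 rose 1.70-fold, AGO3 rose 1.60-fold, PRKRA rose 1.54-fold and TNRC6A rose 1.48-fold. This list's call ended under quantile normalization, cyclic loess and a stricter limit on dim rows (adjusted p between 0.053 and 0.078), and in the unpaired fit without the anti-miR-191 or the control array of experiment 1 (adjusted p = 0.087 and 0.250).

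**Figure D3:**
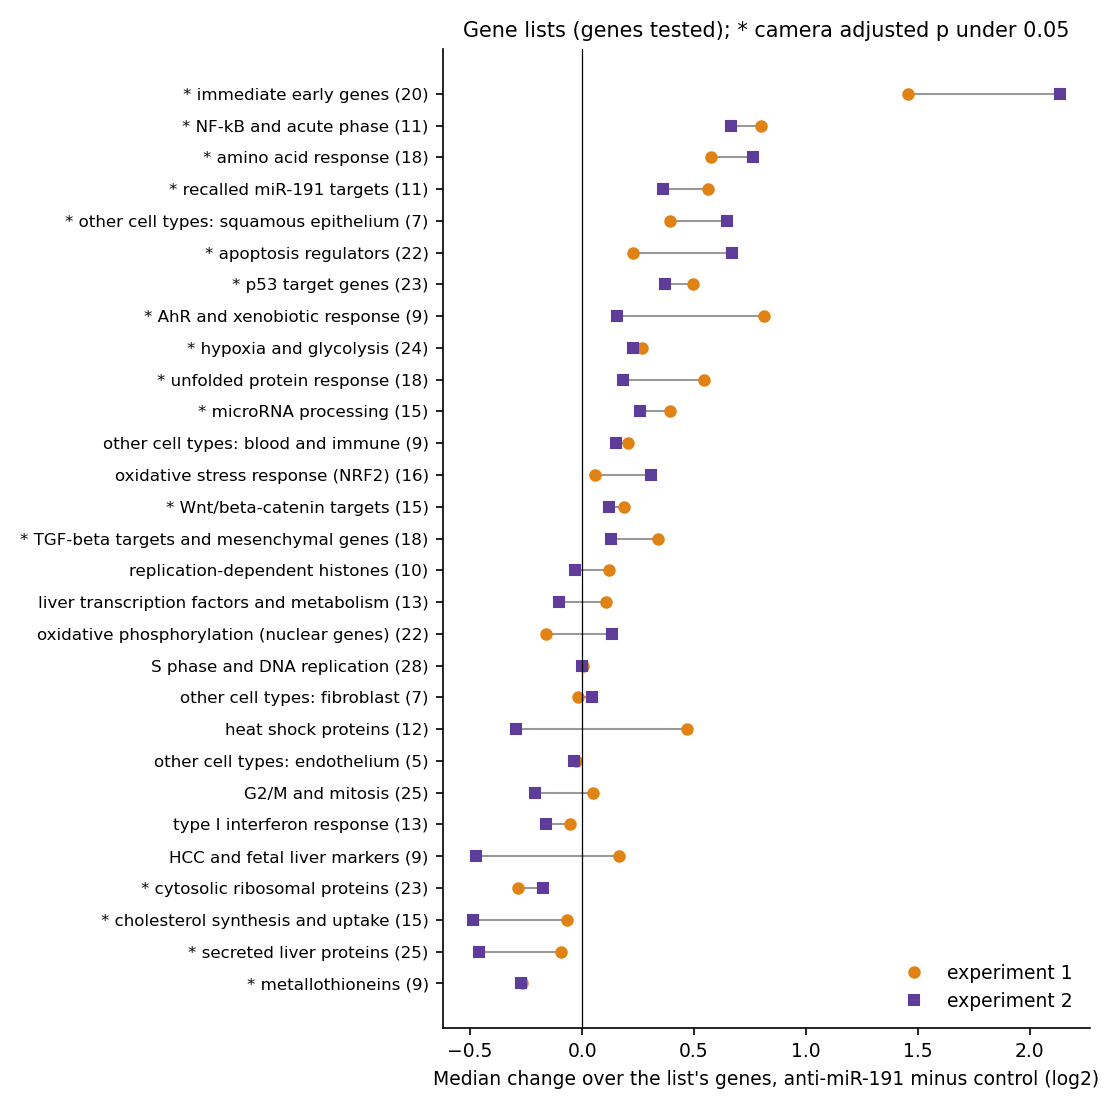
Median change (anti-miR-191 minus control, log2) of the tested genes of 29 lists in experiment 1 (circles) and experiment 2 (squares), with the number of genes tested in brackets and an asterisk where camera's adjusted p was under 0.05 with the preset correlation in the paired fit. Immediate early genes lie farthest to the right, at 1.46 and 2.14, and heat shock proteins lie on opposite sides of 0, at 0.47 and -0.30.

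Secreted liver proteins, cholesterol genes, cytosolic ribosomal proteins and metallothioneins were lower. Of 25 secreted liver proteins 0 rose and 3 fell, also adjusted over the list alone, and 1 was lower in the unpaired fit. They were the apolipoprotein APOC3 (-1.06 ± 0.15), the thyroxine carrier TTR (-1.04 ± 0.14) and clotting factor F10 (-0.67 ± 0.14). The list's median change was -0.09 in experiment 1 and -0.46 in experiment 2 (camera adjusted p = 0.00012; adjusted p = 0.503 with an estimated correlation). CP had changes of 0.03 and -1.15 in experiments 1 and 2, APOB of 0.02 and -1.09, and ALB, the albumin gene, of 0.48 and -0.93. Of 15 cholesterol genes, with a median change of -0.07 in experiment 1 and -0.49 in experiment 2, 0 rose and 3 fell (4 lower adjusted over the list alone, paired fit), with 0 passing in limma's unpaired fit and 2 lower there at an unadjusted p under 0.05. They were DHCR7 (-0.71 ± 0.14), MVD (-0.62 ± 0.16) and FDPS (-0.59 ± 0.14). MSMO1 had changes of 0.06 and -1.15 in experiments 1 and 2, and SC5D, named after its values were seen, of 0.74 and -1.02. This list had a camera adjusted p = 0.0041, and adjusted p = 0.503 with an estimated correlation. In the unpaired fit it lost its call without the anti-miR-191 array of experiment 2 (adjusted p = 0.076) or the control of experiment 2 (adjusted p = 0.079). Of 23 ribosomal protein genes 0 rose and 4 fell, also adjusted over the list alone, with 1 lower in the unpaired fit. RPL7A fell most (-1.06 ± 0.15), then RPS9 (-0.74 ± 0.15), RPS14 (-0.70 ± 0.18) and RPL27A (-0.55 ± 0.14). The list had a camera adjusted p = 0.0041, and adjusted p = 0.503 with an estimated correlation. In the metallothionein list of 9 genes, MT1F (-1.08 ± 0.15), MT1X (-0.66 ± 0.15) and MT1G (-0.61 ± 0.14) fell, MT1F alone also in the unpaired fit, and the zinc exporter SLC30A1 rose 2.16-fold. Adjusted over the list alone, 5 fell and 1 rose. The camera adjusted p was 0.010, with adjusted p = 0.503 with an estimated correlation, and near-identical copies of these genes can share probes. Without the anti-miR-191 array of experiment 1 the unpaired fit gave this list an adjusted p of 0.058.

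Cell cycle genes as lists did not pass the test. Of 28 genes of S phase 2 rose and 1 fell, CCNE1 (2.02-fold), SLBP (1.56-fold) and CDT1 (-0.54 ± 0.15), with 1 higher and 0 lower adjusted over the list alone. CDC6 had changes of 1.22 and 0.04 in experiments 1 and 2. Of 25 mitotic genes, the phosphatase gene CDC25C rose 1.97-fold, and PTTG1 (-0.70 ± 0.15) and UBE2C (-0.64 ± 0.14) fell, also adjusted over the list alone. MKI67 had changes of -0.20 and -0.87. In limma's unpaired fit 0 genes of either list passed, with 4 at an unadjusted p under 0.05 in each. The camera adjusted p was 0.753 for S phase and 0.162 for mitosis. For S phase the median and mean change were 0.02 and 0.04 while camera, which compares the list with all other genes, gave a direction of down. The median change of all genes was 0.01, but camera compares means of moderated statistics, and over all genes 1428 rose while 533 fell. The mean statistic of all genes was not examined here, so the reason for this difference in sign is not shown. Without the anti-miR-191 array of experiment 2 or the control of experiment 1, the unpaired fit called the mitotic list lower (adjusted p = 0.030 and 0.0014).

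The interferon, NRF2, oxidative phosphorylation and histone lists did not pass the test, although some members did. Of 13 interferon-induced genes 0 rose and 3 fell, also adjusted over the list alone, with 1 lower in the unpaired fit. The fallen genes were BST2, ISG15 (-0.74 ± 0.16) and IFI27 (-0.69 ± 0.15), and the list had a camera adjusted p = 0.064. This became 0.041 with dim rows kept, and in the unpaired fit 0.015 and 0.018 without the anti-miR-191 array of experiment 1 or the control of experiment 2. Of 16 NRF2 targets 5 rose and 0 fell, also adjusted over the list alone, with 2 higher in the unpaired fit. They were SLC7A11, SRXN1 (2.06-fold), ABCC2 (1.79-fold), GCLM (to a level of 4.81, from a dim control level) and GCLC (1.64-fold). The list's camera adjusted p was 0.087, with 0.041 when dim rows were kept and 0.039 in the unpaired fit without the control of experiment 1. Of 22 nuclear genes of oxidative phosphorylation 1 rose and 4 fell (2 lower in the unpaired fit, and 1 and 5 adjusted over the list alone), with COX5B (-1.38 ± 0.17), COX6C (-1.10 ± 0.15), NDUFB8 (-0.83 ± 0.15) and SDHC (-0.67 ± 0.15) lower and NDUFB5 1.62-fold higher. Its median change was 0.03 and its mean change -0.11 (camera adjusted p = 0.208), and it passed in the unpaired fit without the anti-miR-191 array of experiment 2 (adjusted p = 0.042). Among 10 replication-dependent histone genes H2BC21 (2.87-fold) and H4C8 (2.12-fold) rose and H1-2 fell by 0.58 ± 0.14 (camera adjusted p = 0.774), with 2 higher and 2 lower adjusted over the list alone and, at an unadjusted p under 0.05, 2 higher and 1 lower in limma's unpaired fit, where 0 passed.

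Heat shock and liver identity lists differed little on average. Of 12 heat shock genes DNAJB1 alone rose (2.02-fold, also adjusted over the list alone), and the list's median change was 0.47 in experiment 1 and -0.30 in experiment 2 (camera adjusted p = 0.753). Its overall median of -0.02 and mean of 0.03 differ in sign. Of 13 liver transcription factors and metabolic genes CYP27A1 alone fell (-0.56 ± 0.15; 0 lower adjusted over the list alone; camera adjusted p = 0.824). SLC2A2 had a change of 0.59 ± 0.17 (adjusted p = 0.063), and the list's median of 0.08 stood against a camera direction of down. None of 9 markers of hepatocellular carcinoma and fetal liver passed in the paired fit (0 also adjusted over the list alone, limma, with 2 lower at an unadjusted p under 0.05; camera adjusted p = 0.139). Among them AFP had changes of 0.16 in experiment 1 and -1.24 in experiment 2, and MDK of -0.26 and -0.49. In the unpaired fit this list was called lower without the anti-miR-191 array of experiment 1 (adjusted p = 0.048) or the control of experiment 1 (adjusted p = 0.029).

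Markers of other cell types were tested as a check on the cultures. None of 7 fibroblast genes passed (limma, 0 at an unadjusted p under 0.05; median change 0.01; camera adjusted p = 0.753). Of 9 blood and immune genes ITGAM alone rose (level 4.88 against a dim 4.19 in controls; camera adjusted p = 0.738), and of 5 endothelial genes ESAM alone rose (2.29-fold; camera adjusted p = 0.824), against an endothelial median of -0.04 and mean of 0.19. Of 7 squamous epithelial genes S100A2 rose 1.89-fold, 5 were higher adjusted over the list alone, and the median change was 0.48 (camera adjusted p = 0.024; adjusted p = 0.503 with an estimated correlation). SFN, KRT16 and LAMB3 had changes of 0.56, 0.55 and 0.48 with adjusted p of 0.051, 0.055 and 0.087. The squamous list lost its call in the unpaired fit without the anti-miR-191 array of experiment 1 (adjusted p = 0.058) or the control of experiment 2 (adjusted p = 0.087). KRT5 and KRT14 had changes of 0.03 and -0.01. The list was thus called in the same direction as the immediate early and stress lists, with S100A2 alone past the threshold over all genes. No mitochondrially encoded gene was measured by a probe set with a single gene symbol, so that sign of RNA quality was not analysed here.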

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

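The tests of histone genes, of other short gene families, of squamous keratins and of random lists for the recalled targets were chosen only after the results they bear on had been seen, and the others were set before their results were seen.

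In the 2 experiments, 25 genes changed by at least 1.5-fold in opposite ways, which stood out as a difference between experiments and was not tested, since each experiment holds 1 array per group. Of these, 17 were higher in experiment 1 and lower in experiment 2. Among them, named after their values were seen, were the chaperones HSP90AA1 (0.65 and -0.75) and HSPH1 (0.65 and -0.68), the nucleolar protein gene NCL (0.63 and -1.02) and ACSL4 (1.08 and -0.95).

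Among 7263 rows with several or no gene symbols, which the comparisons did not use, 375 were at least 1.5-fold higher after anti-miR-191 than in controls in both experiments, 281 were lower and 91 changed in opposite ways.

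The first pattern weighed was the rise of the immediate early genes, with a median change of 1.82. Scaling between arrays is argued against as the cause, since the list's median was at least 1.783 under median centring, quantile normalization and cyclic loess. A single deviating array is argued against by a median of at least 1.551 with any 1 array left out. At most 20% of the tested markers of any other cell type, 1 of 5 endothelial genes, changed over 2-fold the same way in both experiments. This argues against RNA from another cell type as the whole cause. The squamous list was called higher (median 0.48, camera adjusted p = 0.024, 5 of 7 higher adjusted over the list alone), but had an adjusted p = 0.503 with an estimated correlation. Its members KRT16, KRT5 and KRT14 had changes of 0.55, 0.03 and -0.01, from control levels of 4.29, 4.26 and 5.39 that are not shown to be above background. These keratins therefore neither show a smaller share of such RNA nor exclude it. An effect of miR-191 inhibition and an effect of this particular oligonucleotide on the cells may both remain, because the design holds 1 anti-miR-191 and 1 control oligonucleotide and no untransfected cells.

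The second pattern was the fall of respiratory chain and ATP synthase subunits, a gene group drawn up after the named genes had been seen. Of 81 tested, 38 fell and 3 rose, with a median change of -0.47 (-0.57 and -0.51 in experiments 1 and 2). Its bootstrap SE of 0.10 is over genes of the same arrays and holds no spread between experiments. The 22 oxidative phosphorylation genes fixed beforehand instead had a median of 0.03 (4 fell, 1 rose, camera adjusted p = 0.208). A trend with the gene's genomic span could be a source, since change and span correlated across genes (Spearman rho = 0.232), but after its removal the subunits still lay -0.4448 from the other genes. After removal of a trend with mean level they lay -0.526 from them. The 63 histone genes were called lower too (11 fell, 5 rose, camera adjusted p = 0.0096, and 0.695 with an estimated correlation). Their median lay 0.36 above that of the subunits (bootstrap SE over genes 0.12), with histone medians of -0.15 and -0.16 in experiments 1 and 2. For these genes this argues against a lower yield of all short transcripts alike as the whole cause. The short SNORA, MT, SNORD and OR families were also called lower, with medians of -0.46, -0.37, -0.12 and -0.11. MIR, KRTAP, LCE and RNU were not, with medians of -0.10, -0.06, -0.11 and 0.08. MIR and LCE thus lay near SNORD and OR, so the call alone does not part them. Whether these families read above background was not analysed here. For SNORD the experiments differed in sign (-0.38 and 0.05), and with an estimated correlation camera gave the 4 families called lower an adjusted p = 0.695. A lower yield of some short classes stays open beside a biological change, and transcript length itself was not analysed here.

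The third pattern was the rise of the recalled miR-191 targets. Their median change of 0.52 lay at percentile 99.31 of 10000 random lists matched on mean level, but such lists take genes as independent, so chance stays open. Camera with an estimated correlation gave adjusted p = 0.503 (0.391 in the unpaired fit). It cannot decide this, since it has 1 residual degree of freedom (2 unpaired) and the correlation it estimated was -0.018 (-0.055 unpaired). Without EGR1, the 1 member held by another fixed list, the remaining 10 had a median of 0.49 at percentile 99.22. A median of 11 genes can move little when 1 is removed, so this cannot decide whether a shared response raised the list. The random lists were not matched on genomic span, with which change correlated across genes (Spearman rho = 0.232), so that trend stays open as well. Release from miR-191 may be an explanation, but sites for it in the recalled genes' transcripts were not analysed here, and the recalled list has no source at hand.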

How the results depend on the processing

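The tests with treat against a 1.2-fold change, without the immediate early genes in the fit and without them in other lists were chosen after seeing the data. The unpaired count of 553 genes became 1961 with the replicate block, 1344 at an adjusted p under 0.10 and 0 over all 22198 rows above the dim limit (limma; 4067 rows at an unadjusted p under 0.05, lowest adjusted p = 0.079), and ranged from 0 to 339 with 1 array left out. The paired count of 1961 became 553 with no replicate block and 709 with treat. Under the other filters, scalings and moderation settings both total counts stayed within 1.5 times the main count. The correlation of the experiments' changes was 0.659 with dim rows kept, 0.703 with 50% of the rows left out as dim, 0.604 over all rows and 0.750 in the brighter part of the genes. The count of genes changed the same way became 1941 over all rows, 2434 at 1.3-fold and 285 at 2-fold. With an estimated correlation camera called 0 lists in either fit (0 at an unadjusted p under 0.05), and fry called 0 in the unpaired fit (14 at an unadjusted p under 0.05) and 1 in the paired fit, the TGF-beta list (adjusted p = 0.032). The number of lists called by camera was otherwise within 1.5 times the main number. The block changed the call of 2 lists, TGF-beta and Wnt, and of no other list. The Wnt list also lost its call without the immediate early genes (adjusted p = 0.068). Over all settings, single named genes lost a call in 128 cases, 74 of them without the block, and gained one in 5. No paired fit with a test can be had with an experiment left out, and the changes of each experiment are given in the text for some genes and lists. The cause of these differences was not tested. In leave-out fits the lone array is assumed to vary like the other group. Seed sites were not run. The number of arrays, 2 per group, limits which smaller changes can be shown.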

Other observations

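Gene families, grouped by the letters that open their symbols, were examined after the data had been seen, in 102 families with at least 15 tested genes. By camera with the preset correlation 19 passed, 9 higher and 10 lower, and all had an adjusted p = 0.695 with an estimated correlation. The lower families held many short genes. Of 53 SNORA genes, small nucleolar RNAs that guide pseudouridylation, 12 fell and 0 rose, with medians of -0.54 and -0.34 in experiments 1 and 2 (camera adjusted p = 1.5e-14). Of 41 NDUF genes of complex I, 19 fell and 3 rose (medians -0.53 and -0.52, camera adjusted p = 9.6e-06). Of 19 ATP5 genes of ATP synthase, 9 fell and 0 rose (medians -0.48 and -0.51). The list of oxidative phosphorylation genes fixed beforehand had a median of 0.03. Of 81 cytosolic ribosomal protein genes, 16 fell and 3 rose.

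The 9 higher families were KDM, RBM, DDX, EIF, USP, DHX, GTF, ZBTB and ZNF. They were grouped by symbol alone, a shared function was not tested, and in DHX 0 of 16 genes rose. Of 18 KDM genes, histone demethylases, 8 rose and 0 fell, with medians of 0.60 and 0.48 (camera adjusted p = 0.00016). Of 29 RBM genes of RNA-binding proteins 7 rose and 0 fell, and of 27 DDX helicase genes 6 rose and 0 fell. Among 272 ZNF zinc finger genes 53 rose and 0 fell, with medians of 0.10 and 0.13 (camera adjusted p = 0.018). Of 49 EIF translation factor genes 12 rose and 2 fell.

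By genomic span, the tenth of genes with the shortest spans (median 1.59 kb) held 55 genes that rose and 155 that fell, with a median change of -0.10. The tenth with the longest spans (median 216 kb) held 149 that rose and 10 that fell, with a median change of 0.06. The correlation of change and span across genes was 0.291 in experiment 1 and 0.124 in experiment 2.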
